A study of Gallus gallus with 3 samples.

How the data were processed

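Gene expression was measured by RNA sequencing in 3 libraries of whole chicken embryos at Eyal-Giladi stage X, each from a pool of 20 to 30 embryos. Per the labels' protocols, RNA was extracted with an RNeasy column kit and libraries were made with the TruSeq RNA kit, version 2. Bowtie, a short-read aligner, is the one tool named per the submitters' processing notes. Its version and settings, the genome build, the gene annotation and any filters are not given in the sources used here. Whether counting used strand, and how reads shared by near-identical genes were treated, is not given either, so values of paralogs and overlapping genes are uncertain.

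For each library the authors deposited 1 table without a header, with a gene identifier, a cRPKM value and a read count. The deposited counts are whole numbers, 1 per gene, and are not normalized. The deposited cRPKM values are RPKM values (read counts scaled to gene length and library size) with 2 decimals, corrected by the authors, and the file names give the unit. The length and library size behind the cRPKM were worked out from the values. How the corrected length differs from the plain gene length was not, since a plain length would be whole too. A gene's read count divided by its cRPKM and by the library's sum of counts gives the number of positions the authors divided by, called the effective length here. It came out whole (within 0.1) for 985 of 985 genes in pool a, 983 of 983 in pool b and 978 of 978 in pool c, the genes for which rounding of the cRPKM leaves less than 0.05 positions of doubt. The library size behind the cRPKM is therefore the sum of reads counted on the listed genes. Effective lengths ran from 1 position upward with a median of 1828, for 15717 genes with a nonzero value. A gene with few positions reaches a high cRPKM from few reads, and this affects its precision. Of 16958 listed genes, 300 were NA for both values in every library and were left out, and 57 had reads but were listed at 0.00 in every pool.

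The labels give 1 group of 3 replicates, so no test between groups was made. A gene was called detected at 1 cRPKM or more in each pool. Agreement used log2(cRPKM + 1), and a difference on this scale understates the change of low genes. To ask whether pools differed by more than counting error, each gene's 3 read counts were compared with their expectation from the library sizes by a chi-square test with 2 degrees of freedom, for genes with a mean of at least 10 reads, with Benjamini-Hochberg adjustment. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), and edgeR's common dispersion of a model with an intercept alone gave the overall spread. edgeR's quasi-likelihood test was not used, since it has no contrast here. Reads carry no molecular identifiers, so they need not be independent molecules. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The coefficient of variation that counting error gives was taken from Poisson counts at each gene's mean, as the mean of the median over 200 draws. Deviations of a pool are log2 TMM-scaled counts (0.5 added) minus the gene's mean over pools.

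The chi-square test was checked on counts simulated from the real genes' means and library sizes, with 200 genes changed in 1 pool. The counts were Poisson draws, with no spread between pools beyond counting error. Among 13858 genes tested it called 66.0% of 50 genes changed by 1.25-fold, 84.0% of 50 at 1.5-fold (1 of which was not tested, having too few reads), 90.0% of 50 at 2-fold and 100% of 50 at 4-fold. Of 13659 unchanged genes it called 10. That low count follows from the draws, which meet the test's own assumption. These rates therefore do not carry over to the real pools, which spread by more than counting error.

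The depth was 140187132 counted reads in pool a, 135502157 in pool b and 137811639 in pool c. Intervals of shares are exact (Clopper-Pearson) binomial intervals at 95%, and a count of 0 was given a limit of 3 reads.

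Before the data were examined, 18 gene lists with 359 genes (among them pluripotency, hypoblast, primitive streak, neural, germ cell and splicing regulator genes), 10 contrasts between lists and 35 pairs of related genes were fixed. None was run: neither the files nor the reference table used here (RefSeq genes of assembly GRCg7b, 25635 rows, 0 of them with an Ensembl identifier) pairs the identifiers with symbols, and 0 identifiers matched. The rule for named genes asked for symbols of list members and pairs, the 10 highest genes and the 10 with the largest SD among genes at a mean of 5 cRPKM or more. It also asked for a fixed set of single genes, among them NANOG and DAZL, which could not be looked up. Only the parts on the 10 highest genes and the 10 largest SDs were applied, without the symbol. A few of these genes are printed by identifier and the rest as ranges. The detection threshold, the chi-square test with its scaling and minimum of reads, and most alternatives to them were also set before the data were examined. The classes of level and of read count, the ratio of 1.5, the minimum of 100 positions, the corrections for length and level, the detection rule of 1 cRPKM with at least 10 reads, and the run of neighbouring identifiers with the count made without it were chosen after. Alternatives covered the detection threshold and rule, the pseudocount (0.1), the scaling (total counts, DESeq2 1.42.0 size factors, a median-of-ratios factor for cRPKM), the minimum of reads, and leaving out each pool.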

Results

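RNA was measured in whole chicken (Gallus gallus) embryos at Eyal-Giladi stage X, the blastoderm that lies on the yolk at about the time the egg is laid. The series belongs to an atlas of alternative splicing across vertebrate tissues and cell types. The files analysed here hold gene expression, not splicing. All 3 libraries form 1 group, and each was made from a pool of 20 to 30 embryos. The pools are called a, b and c after the labels. With 1 group the design implies no contrast between conditions. The questions it allows are which genes were expressed in the stage X embryo, at what level, and how far the 3 pools agreed. The labels do not say whether the pools were collected on separate occasions, so the spread between these libraries may be technical. The p-values below measure only how far a gene's reads depart from counting error, with each read taken as an independent draw. They become smaller with depth and are not tests of pools as replicates. The depth was 140187132 reads counted on genes in pool a, 135502157 in pool b and 137811639 in pool c. Genes appear under Ensembl identifiers, which the files do not pair with names.

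At a threshold of 1 cRPKM, the larger part of the measured genes was expressed in every pool of stage X embryos. Of 16658 genes with a value, 10459 (62.79%) reached 1 cRPKM in each of the 3 pools, where cRPKM is the authors' corrected RPKM, a read count scaled to gene length and library size. Single pools reached this level for 10652 ± 37.6 genes (SD, n = 3). A further 397 genes reached it in some pools but not all, and 5802 genes stayed below it in every pool. The genes detected in every pool had a median of 15.5 cRPKM, with quartiles of 5.10 and 42.9. No read was counted for 884 genes in any pool. A count of 0 allows up to 3 reads in a library, which is 0.0214 RPM in pool a, 0.0221 in pool b and 0.0218 in pool c. These limits, and the intervals below, cover counting error only. Genes below the threshold still had reads, though no background level was estimated to show that these came from their transcripts. At least 10 reads in each pool were counted for 3205 genes that did not pass 1 cRPKM in every pool. The opposite also occurred, since 42 genes passed 1 cRPKM in every pool with fewer than 10 reads in at least one of them.

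**Figure D1:**
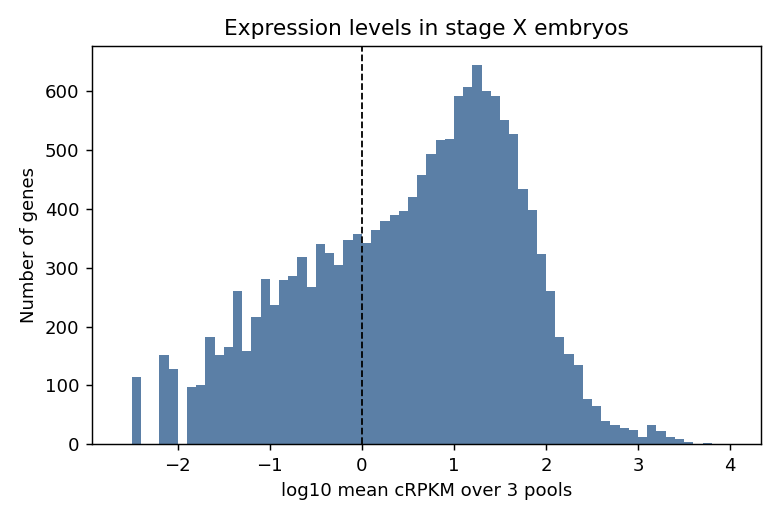
Number of genes (vertical axis) by log10 of the mean cRPKM over the 3 pools (horizontal axis), for genes with a mean above 0. The dashed line marks 1 cRPKM, the main mode lies to its right, and the gaps at the far left come from values deposited with 2 decimals.

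Most reads fell on genes from 10 to 1000 cRPKM, and a small set of very abundant genes took a sizeable part of the reads. The 96 genes at a mean of 1000 cRPKM or more took 16.15% ± 0.41 of the counted reads (SD, n = 3). The 997 genes from 100 to 1000 cRPKM took 34.9% ± 0.10. The largest part, 43.6% ± 0.44, fell on the 5271 genes from 10 to 100 cRPKM. The 4281 genes from 1 to 10 cRPKM took 5.08% ± 0.10, and the 6013 genes below 1 cRPKM took 0.297% ± 0.0098. Of the summed cRPKM, which allows for effective length, these classes held 30.1% ± 0.80, 37.6% ± 0.15, 29.1% ± 0.58, 2.93% ± 0.082 and 0.217% ± 0.0079, from the highest class to the lowest. The 10 genes with the most reads in a pool held 5.82% ± 0.046, the top 100 held 20.2% ± 0.30 and the top 1000 held 55.5% ± 0.30. The most read 767 ± 12.8 genes of a pool held 50% of its reads. These classes were stable between pools: 15860 genes (95.21%) fell into the same class in all 3 pools. The most abundant genes were short in terms of the positions that the authors counted over. The median effective length was 690 positions at 1000 cRPKM or more, 1320 from 100 to 1000 cRPKM, 2168 from 10 to 100 cRPKM and 1391 below 1 cRPKM. Across all genes with a known length, level and effective length were only weakly related (Spearman's rho = 0.11 across 15717 genes, which are not independent replicates).

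The gene with the highest level was ENSGALG00000015917, at 6335 ± 80.5 cRPKM (SD, n = 3) over 1635 positions. It took 1.050% of the reads in pool a (exact 95% binomial interval 1.048 to 1.052), 1.024% in pool b (1.022 to 1.026) and 1.034% in pool c (1.032 to 1.035). ENSGALG00000004509 followed at 5707 ± 113 cRPKM over 173 positions, so it needed far fewer reads for a similar level. The 10 genes with the highest mean lay between 2885 and 6335 cRPKM, and their effective lengths ran from 66 to 1635 positions. Those ranked 4, 6, 8, 9 and 10 belong to a run of neighbouring identifiers described below.

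The 3 pools gave nearly the same ranking of genes. Spearman's rho across the 16658 genes was 0.994 for each pair of pools. Pearson's r of log2(cRPKM + 1) was 0.9987 between pools a and b, 0.9982 between a and c and 0.9983 between b and c. These are correlations across genes, which are not independent replicates. The SD of a gene's log2(cRPKM + 1) over the 3 pools had a median of 0.066 among genes detected in every pool. The SD over genes of the log2 difference was 0.126 between pools a and b, 0.146 between a and c and 0.143 between b and c. No pair of pools behaved as a library deposited more than once, since 5137 genes differed between a and b, 6833 between a and c and 6482 between b and c (chi-square test of the read counts, Benjamini-Hochberg adjusted at 0.05). Of these, 154, 344 and 273 genes differed by 1.5-fold or more.

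Most genes varied between pools by more than counting error, yet by small amounts. Of 13871 genes with a mean of at least 10 reads, 8479 (61.13%) departed from equal shares of the 3 libraries (chi-square test with 2 degrees of freedom, TMM-scaled library sizes, Benjamini-Hochberg adjusted at 0.05). At an unadjusted p under 0.05 there were 8907. The called share rose with the read count. It was 279 of 2305 genes with 10 to 100 reads and 1240 of 3147 with 100 to 1000. It was 4004 of 5204 with 1000 to 10000, 2789 of 3047 with 10000 to 100000 and 167 of 168 above. The 61.13% therefore depends on depth. The median ratio of highest to lowest pool among the 8479 was 1.125. A ratio of 1.5 or more was seen in 488 of them, and a ratio of 2 or more in 137. The square root of edgeR's common dispersion, a coefficient of variation beyond counting error, was 6.93% over the 3 pools. It was 5.14% for a with b, 8.11% for a with c and 7.25% for b with c. With pool c left out the count was 5137 genes in all and 154 at 1.5-fold; with pool a left out it was 6482 and 273, and with pool b left out 6833 and 344. A test on 2 pools has fewer reads and a smaller range by construction.

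The spread in excess of counting error, as a coefficient of variation, fell with the read count of a gene up to 100000 reads. As the square root of the mean relative variance beyond counting error, it was 21.3% for genes with 1 to 10 reads and 12.99%, 10.1%, 7.02%, 5.16% and 5.57% for genes with 10 to 100, 100 to 1000, 1000 to 10000, 10000 to 100000 and more reads. Chi-square per degree of freedom rises with the reads at any fixed relative spread. For genes with 1 to 10 reads its mean was 1.13, where counting error alone gives 1. It was 1.67 for genes with 10 to 100 reads, 4.68 with 100 to 1000, 19.3 with 1000 to 10000, 64.7 with 10000 to 100000 and 832 above 100000. The median coefficient of variation over the 3 pools fell over the same 6 classes, from 47.1% at 1 to 10 reads to 17.8%, 8.71%, 5.28%, 3.78% and 3.73%. Counts drawn from Poisson at the same means gave medians of 45.1%, 13.96%, 4.42%, 1.365%, 0.559% and 0.198%. The genes with a called ratio of 1.5 or more were mostly of low count: 266 had 10 to 100 reads, 181 had 100 to 1000, and 41 had more. A call at low count takes a large ratio, and 266 of the 279 genes called at 10 to 100 reads passed 1.5-fold. At 1000 to 10000 reads it was 37 of 4004. The low-count share therefore does not show that genes of low level vary more. Over all 8479 called genes, pool a was the highest for 34.7%, pool b for 29.4% and pool c for 35.9%, and they were the lowest for 30.8%, 27.1% and 42.1%. At a ratio of 1.5 or more, pool c was the highest for 252 of the 488 genes (51.6%), pool a for 146 and pool b for 90. Pools a, b and c were the lowest for 170, 165 and 153 of them.

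**Figure D2:**
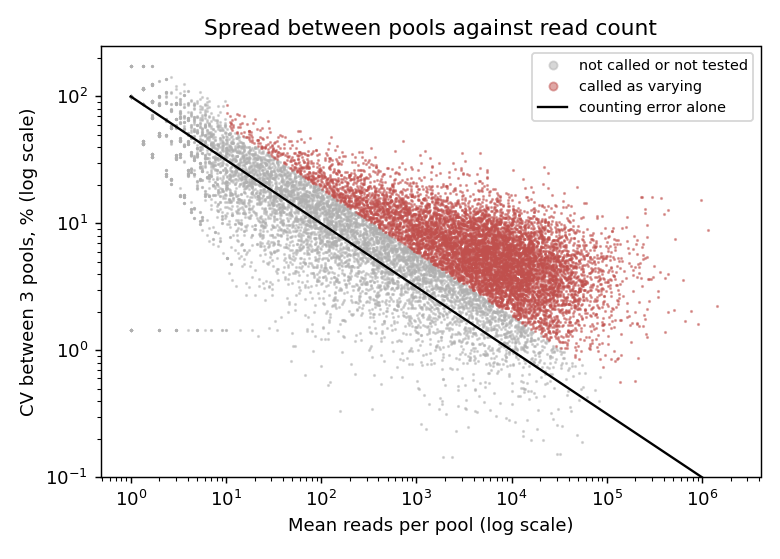
Coefficient of variation between the 3 pools in percent (vertical axis, log scale) against mean reads per pool (horizontal axis, log scale), 1 point per gene, with the line that counting error alone gives. Points of genes called as varying lie above the line, and at high read counts the cloud levels off near a median of 3.73% while the line goes on falling.

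Pool a held slightly more of the short genes and pool b slightly more of the long ones. Among 10340 genes with at least 1 cRPKM and 100 reads on average, the 25% of genes with the fewest positions (up to 1237) lay at a median log2 deviation of 0.032 in pool a and -0.026 in pool b. The 25% with the most positions (from 3395) lay at -0.0093 in pool a and 0.016 in pool b. Spearman's rho of the deviation with effective length was -0.20 in pool a, 0.20 in pool b and 0.0094 in pool c. With the mean cRPKM, rho was 0.19 in pool a, -0.012 in pool b and -0.17 in pool c. These are correlations across genes, given with no p-value.

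The genes with the largest relative spread were mostly genes with very few countable positions. Among genes with a mean of at least 5 cRPKM, 6 of the 10 with the largest SD of log2(cRPKM + 1) had fewer than 100 positions, and 4 had a mean of fewer than 10 reads. The first, ENSGALG00000026320, had 1 position. It was listed at 21.4 cRPKM in pool a, 0 in pool b and 21.8 in pool c, which were 3, 0 and 3 reads. The count of 0 in pool b allows up to 22.1 cRPKM at that length, so no difference was detectable. Of the 10, 5 were called as varying. One of these, ENSGALG00000022674, had 5 positions but 1526, 901 and 834 reads in pools a, b and c, a ratio of 1.84 between the highest and lowest pool (chi-square test, adjusted p = 2.49e-56). Restricted to genes of 100 positions or more, the 10 largest SDs ran from 0.39 to 0.54, with ratios of highest to lowest pool from 1.63 to 2.43, and all 10 were called.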

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

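The count of 10459 detected genes stayed within 1.5 times under the 9 alternatives set beforehand and under 1 added later. The later one, 1 cRPKM with at least 10 reads in each pool, gave 10417 genes. The count was 11451 at 0.5 cRPKM, 9389 at 2 cRPKM and 7724 at 5 cRPKM. With at least 10 reads in each pool as the rule it was 13622. At 5 cRPKM the detected genes were the smaller part of the 16658 measured, so that statement depends on the threshold. The mean Spearman correlation between pools was 0.994, was 0.997 when only genes with a mean of at least 1 cRPKM were kept, and lay between 0.9943 and 0.9944 with 1 pool left out; the shift under the filter is larger than the spread over pairs (SD 7.8e-05). The 8479 varying genes were 8596 with total counts and 8479 with DESeq2 size factors, which shared 8058 and 8433 genes with the 8479. With 1 pool left out the count ran from 5137 (without pool c) to 6833 (without pool b), and the 488 genes at 1.5-fold ran from 154 (without pool c) to 344 (without pool b), with 273 without pool a. Fewer pools give fewer reads and a smaller range by construction. At a minimum of 50 reads 364 genes passed 1.5-fold. Depth limits calls among genes with 10 to 100 reads, where counting error alone gives a median coefficient of variation of 13.96%. Alternatives for the gene lists, list contrasts and gene pairs were not run, because the identifiers could not be matched to symbols.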

Other observations

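In this part, the following were chosen or worded only after the results were seen: the run of identifiers with its window of 30 numbers, its cut at 500 cRPKM and its pool a, the corrections for length and level, the test of genes with few positions against genes matched on reads, the tests of the scaling and of the level for the run and the test of consecutive identifiers.

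A run of neighbouring identifiers held very abundant genes, 10 of 13 of them highest in pool a. Of 181 genes with a mean over 500 cRPKM, 13 fell within 27 consecutive identifier numbers, and no other window of 30 numbers held more than 4. The run includes ENSGALG00000018373, ranked 4 by mean cRPKM, at 5535 cRPKM in pool a, 4639 in pool b and 4198 in pool c. It also includes the genes ranked 6, 8, 9 and 10. The 13 genes together took 3.15% of the reads in pool a, 2.73% in pool b and 2.49% in pool c. Of the 13, 12 were higher in a than in c and 10 were higher in a than in b, with median ratios of 1.28 and 1.20. The other 14 genes of the run had up to 422.6 cRPKM, and 10 of them were also highest in pool a. ENSGALG00000018366 had 302 effective positions and the rest of these had 16 to 25. Some of the 10 rest on few reads and small gaps. ENSGALG00000018362, with a mean of 79.7 reads, had log2 deviations of 0.053 in pool a and 0.049 in pool b.

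Technical explanations were weighed for this run. The run was noticed because several of its genes were higher in pool a, so its median log2 deviation of 0.204 in that pool is not a test of itself and may overstate the difference. A library's scaling factor shifts all its genes alike, but the other 168 genes over 500 cRPKM had a median of 0.04754 in pool a, with quartiles of 0.017 and 0.080, so scaling as the whole cause is argued against. A trend with level as the whole cause is argued against too, since 75.72% of the run's deviation was left after correction for mean cRPKM; this rests largely on the same other abundant genes and is not separate evidence. Correction for the trend with effective length left 84.6%. What stays open is a difference in RNA extraction, handling or batch between pools, for which the labels give no record, and a difference in the embryos themselves. What the genes of the run are was not determined, because the identifiers could not be paired with names. What they may have in common was not determined either, and their effective lengths were not compared with those of known genes. No biological explanation was tested, because the design has 1 group.

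Genes with consecutive identifiers did not in general deviate together: Spearman's rho of their deviations in pool a was 0.0173 over 3275 pairs of neighbours with at least 1000 reads each (0.0058 in pool b, 0.0083 in pool c). The parallel change in the run is therefore not a general property of neighbouring identifiers in these files.

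The variation of most genes between pools was weighed against technical explanations. The choice of scaling changed few calls, since at least 95.03% of the 8479 calls were kept under total counts or DESeq2 size factors. The TMM factors lay between 0.988 and 1.011, so these scalings lie close together and the share kept could not decide about scaling. A scaling factor shifts all genes of a library alike. Among the 8479, however, pool a was the highest for 34.7%, pool b for 29.4% and pool c for 35.9%. These shares were taken after TMM scaling, which centres each library, so their near evenness follows in part from the scaling. Each pool was also the lowest for many of the 8479, at 30.8%, 27.1% and 42.1% for a, b and c. A shift of all genes alike cannot raise some genes of a pool and lower others. Scaling as the whole cause is therefore argued against. The trend with effective length as the whole cause is argued against too, since 93.7% of the calls were kept after its correction; a correction for the trend with level kept 93.99%. Library preparation, sequencing batch and true differences between the pooled embryos stay open, as the labels give neither a batch nor a second group.

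The large relative spread of genes with few countable positions may, for the set as a whole, follow from their few reads. The 117 genes with under 100 positions and at least 5 cRPKM had a median coefficient of variation of 12.07%, and genes of 100 positions or more matched on reads had 12.03%, a ratio of 1.004. Poisson counts at the same means gave 7.62% and 7.58%, so both sets varied by more than counting error, and 26 of the 112 short genes tested (23.2%) were called as varying, against 27.0% of the matched ones. ENSGALG00000022674, with 5 positions and a called ratio of 1.84, is 1 of the short genes whose spread counting error does not give. A cRPKM threshold alone therefore mixes genes of very different precision: 271 genes at a mean of 1 cRPKM or more had under 100 positions.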
